A study of Drosophila melanogaster with 16 samples.

How the data were processed

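Gene expression was measured in whole Drosophila melanogaster embryos on 16 oligonucleotide arrays, 1 per sample, in 4 groups of 4. Wild-type (Oregon-R) embryos were compared with sca-gcm embryos, in which the driver scabrous-GAL4 switches on UAS-gcm across the neuroectoderm. The sca-gcm embryos come from a cross of scabrous-GAL4 to a yw line with UAS-gcm. Genotype and strain background thus differ together, and no embryos with the driver or UAS-gcm alone are among the samples. Both genotypes were sampled at 6-7 h after egg laying, stage 11, here called early, and at 13-14 h, stages 15 to 16, here called late. Per the labels, RNA came from 200 mg of embryos and cDNA was made from 20 µg of total RNA with a T7 primer, and both genotypes were collected in parallel. The labels do not say whether the 4 arrays of a group come from separate collections, so the p-values measure the spread between these samples, which may be technical. Replicates carry the numbers 1 to 4 in wild type and 7 to 10 in sca-gcm.

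The deposited values are intensity per probe set on a linear scale, with 1 decimal, and some lie below 0. How the authors analysed the images, subtracted background and scaled the arrays is not given in the sources used here. The table held 14070 probe sets, of which 32 were control probe sets and were left out. Probe sets were named by matching their names to gene symbols, older symbols and CG numbers of the reference annotation. This gave 13024 probe sets a single gene, 11268 different genes in all, and left 1014 without a name, 538 of them because the name fitted more than 1 gene. The glial gene repo was matched to no probe set and was not analysed here. The gene para was named from the probe set BSS_at through an older symbol.

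Array medians ranged from 38.6 to 156 and did not lie within 5% of each other, the bound set for taking the arrays as already scaled. The 14038 probe sets were therefore quantile normalized over the 16 arrays. Values below a floor of 103.07, the size of the pooled 5th percentile, were raised to that floor and log2 values were taken. A probe set was tested if it stood above the floor on at least 3 of the 4 arrays of a group, which left 7827 tested and 6211 not tested. A fold against a group with fewer than 3 arrays above the floor is a lower bound and is given as "at least", taken from the fitted log2 means and rounded like the other values. A gene with several probe sets is represented by the one with the highest mean. The other probe sets of bap and of dysf disagreed in direction with the one named, in the late comparison. The number of arrays limits the precision.

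Group means were fitted over all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; residual degrees of freedom 12, prior degrees of freedom 3.32). Contrasts were sca-gcm against wild type early and late, the difference of these effects (late minus early), and late against early within each genotype. Adjusted p-values are two-sided and Benjamini-Hochberg adjusted over the tested probe sets, and a change was called at an adjusted p under 0.05. Values are given as mean normalized intensity ± SD with n = 4, and errors of log2 changes are standard errors of the fit. A group at the floor on all its arrays has no spread but enters the shared estimate. Errors and p-values of such genes can therefore be too small. For alrm, at the floor on all early arrays, the late adjusted p in limma was 0.018, but 0.0644 on the 8 late arrays alone. Other tables and plots were made with Python 3.11.15 and matplotlib 3.10.9.

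There were 16 gene lists, among them markers of other cell types that whole embryos hold. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over lists and contrasts (45 tests of 15 lists). Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move one way on balance and does not compare the list with other genes. The list of strain markers (w, y and sca) had only sca matched to a probe set by name and got no list test. For each list, changed members were also counted with p-values adjusted over the list alone. The relation between the sca-gcm effect and development was taken as Pearson's r across probe sets, with the wild-type arrays of each stage divided so that no array entered both sides.

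Genes named in the text follow a rule. It takes gcm and repo; the 10 largest rises and falls of each stage with both groups above the floor and no overlap between their arrays; the 5 brightest from or to the floor in each direction; changed members of the lists; the 5 largest differences of effect in each direction; and the 10 largest rises and falls of wild-type development. The normalization rule, the tests of the comparisons, the lists and the naming rule were chosen before the data were examined, and tests of explanations were written later.

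The procedure was tested on simulated data with known changes placed among 7258 to 7342 tested probe sets. It recovered 28.4% of the early changes of 1.5-fold, 58.2% of those of 2-fold and 66.7% of those of 4-fold, with 3 unchanged probe sets called. In the late comparison it recovered 29.9%, 50.7% and 68.2%, with 3 called. For the difference of effects it recovered 13.4%, 31.3% and 74.2%, with 9 called, and for wild-type development 31.3%, 52.2% and 66.7%, with 11 called. Most simulated changes of 1.5-fold were thus missed. Each comparison held only 66 or 67 changes of each size, far fewer than the 2077 called late in the real data. Adjusted p-values are stricter with so few changes, so these shares do not carry over to the real comparisons. A gene not called may still have changed. A list of 15 simulated genes raised 1.5-fold gave a camera p of 7.8e-27, and 6 of 200 unshifted lists gave a p under 0.05. The simulated values were drawn for each probe set separately, so the genes were uncorrelated. The real lists had estimated correlations of up to 0.32, in the heat shock list, so these values do not show how camera behaves on them.

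Alternatives were the values as deposited, arrays scaled to the same median, a doubled and a halved floor, a generalised log without a floor, other filters, eBayes with trend and robust settings, array weights, fits of the compared arrays alone, replicate blocks, stricter thresholds, all probe sets of the listed genes, and leaving out each array in turn. Quantile normalization within each stage, the glial list without gcm and a test of the difference between stages over probe sets above the floor in a group of each stage were added after the data were seen.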

Results

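The data are 16 arrays of whole embryos, 4 each of early wild type, early sca-gcm, late wild type and late sca-gcm. Medians of the deposited intensities ran from 38.6 to 60.8 on the early arrays and from 83.1 to 156 on the late ones, and between 19.6% and 25.8% of the values on each array were at or below 0. Within groups, the rank correlation across probe sets between any 2 arrays was 0.892 to 0.936, and any 2 arrays had different values at no less than 99.8% of the probe sets.

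The labels state that gcm, a transcription factor that directs neural precursors to a glial fate, was misexpressed across the neuroectoderm to find genes acting downstream of it. The gene itself (CG12245) was measured at 705 ± 55.3 in early wild-type embryos and at 6649 ± 273 in early sca-gcm embryos (SD, n = 4), a rise of 9.45-fold (95% interval 8.22 to 10.9). In late wild-type embryos gcm was at the floor on all 4 arrays, and in late sca-gcm embryos it stood at 563 ± 66.9, at least 5.43-fold higher. The late fold is a lower bound, so the data do not show at which stage the rise in gcm was larger. Of the strain markers w, y and sca, only sca, the source of the driver's enhancer, was matched to a probe set by name. The probe set W_at, whose name also fits w, was left unnamed and its values are given at the end. For sca the log2 changes in limma were -0.25 ± 0.35 early (adjusted p = 0.854) and -0.13 ± 0.35 late (adjusted p = 0.901). It stood above the floor on only 2 sca-gcm arrays at each stage, so these changes are not exact.

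**Figure D1:**
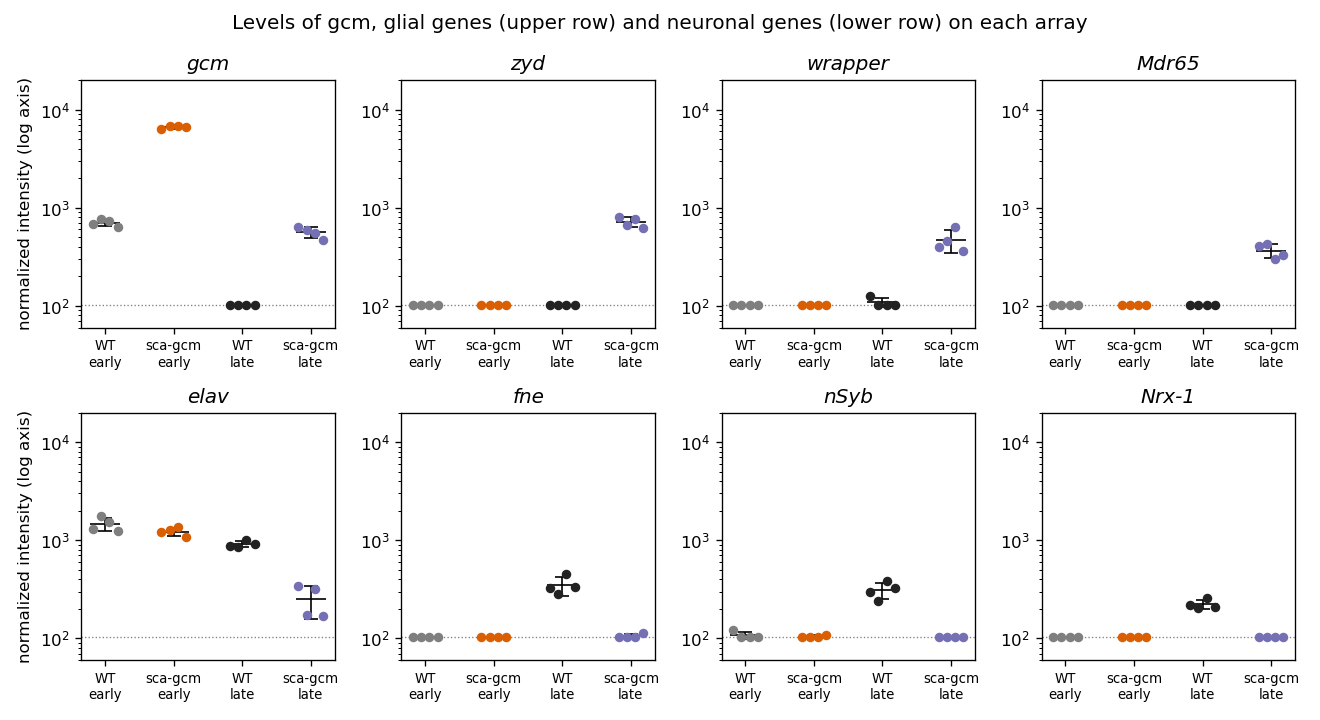
Normalized intensity on each array (log axis) of gcm, zyd, wrapper and Mdr65 in the upper panels and elav, fne, nSyb and Nrx-1 in the lower panels, for the 4 groups; points are arrays, bars the mean ± SD, and the dotted line the floor of 103.07. Late sca-gcm arrays average 715 for zyd, which is at the floor in the other groups, and 249.8 for elav against 917 in late wild type.

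In early embryos, next to gcm the largest rise of a named gene measured in both groups was in Nagk, which encodes an N-acetylglucosamine kinase, from 288 ± 52.8 in wild type to 1512 ± 207 in sca-gcm (5.28-fold, 95% interval 4.38 to 6.37). The metallothionein gene MtnA rose 3.91-fold, Cnx14D, a calnexin-type chaperone of the endoplasmic reticulum, 3.08-fold, and wisp, a poly(A) polymerase of oogenesis, from 185 ± 29.3 to 527 ± 143 (2.79-fold). The cytochrome P450 genes Cyp4e2, from 1552 ± 136 to 464.8 ± 105 (3.40-fold), and Cyp6a8 (3.39-fold) fell, whereas a further one, Cyp4p2, rose from the floor (at least 2.79-fold), and the glutathione transferase genes GstE6 (3.17-fold) and GstE3 (at least 3.11-fold, to the floor) fell. Egfr, the epidermal growth factor receptor, fell from 790.2 ± 104 to 293 ± 36.7 (2.70-fold), and the small heat shock gene Hsp23 from 540.3 ± 67 to near the floor, 106 ± 5.44 (at least 5.08-fold). All values have n = 4, and the adjusted p-values of these genes, from limma, were 3.4e-04 or smaller.

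Of 7827 probe sets tested, 632 changed early, 347 higher and 285 lower in sca-gcm, in 564 named genes. At least 2-fold changes made up 113 of them, 64 higher and 49 lower. The 4 arrays of each genotype did not overlap for 534 of the 632; chance gives 2.86% for probe sets taken at random, but these were selected on the same arrays. Further rises were in DhpD (3.03-fold), the lysozyme gene LysD (3.03-fold), the arginine kinase gene Argk1 (2.59-fold), hpRNA:CR18854 (2.56-fold) and Fitm (2.50-fold). From the floor, CG43740 rose at least 5.76-fold to 594.5 ± 37.6, and PIG-V, mwh and CG5645 at least 2.30- to 2.67-fold. Other falls were in CG33090, from 459.8 ± 63.7 to 114 ± 9.81 (4.02-fold), Tsp42Ec (3.42-fold), CG12546 and CG8799 (3.10-fold each), CG14454 (2.99-fold) and CG33272 (2.86-fold). CG10936, Hsc70-2 and Aplip1 fell to the floor, at least 3.33-fold, and CG13159 at least 2.77-fold (adjusted p = 0.0398).

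Of 14 glial genes tested early, 2 rose and none fell: gcm and drpr, an engulfment receptor of glia, from 349.9 ± 25.3 to 571 ± 20.4 (1.63-fold, adjusted p = 0.00209). Adjusted over the list alone, 3 rose. The list as a whole was not called (camera adjusted p = 0.144; 0.725 without gcm), and its median log2 change was 0.00 beside a mean of 0.27. The glial markers zyd, Mdr65, wrapper and alrm were at the floor on all early arrays of both genotypes.

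Of 21 proneural and neuroblast genes, 5 fell and 1 rose early. The fallers included scrt, a zinc finger factor of neural precursors and neurons, from 930 ± 48.5 to 362 ± 58.8 (2.59-fold), nerfin-1 (1.68-fold) and brat (1.33-fold), and sna rose 1.46-fold. Adjusted over the list alone, 6 fell and 2 rose. The list shifted down (median log2 change -0.22, camera adjusted p = 0.0115; adjusted p = 0.236 with an estimated correlation). Of 17 neuronal and synaptic genes, para (1.36-fold, adjusted p = 0.0351) and Rop (1.28-fold, adjusted p = 0.0483) fell and none rose, 3 fell adjusted over the list alone, and the list was not called (adjusted p = 0.126). In the list of 6 midline genes, Egfr and rho, a protease that activates its ligand, fell (1.34-fold for rho), as they did adjusted over the list alone, and the list shifted down (camera adjusted p = 0.0385; adjusted p = 0.312 with an estimated correlation). Among 14 Notch pathway and Enhancer of split genes, E(spl)m3-HLH rose 2.34-fold, with 1 rise and 1 fall adjusted over the list alone and no shift called (adjusted p = 0.389).

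Markers of other tissues in whole embryos changed as follows in early sca-gcm. Of 16 plasmatocyte and crystal cell genes, the scavenger receptor gene Sr-CI rose 1.85-fold and the collagen gene vkg fell by 0.58 or more on the log2 scale, to near the floor, with 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.126). The septate junction gene crok rose 2.01-fold, alone among 16 (adjusted p = 0.792; median -0.02, mean 0.02), the cuticle gene Edg78E at least 1.52-fold, alone among 12 (adjusted p = 0.83), and svp fell 1.84-fold, alone among 5 fat body genes (adjusted p = 0.324). These counts were equal when adjusted over the list alone. Among 17 cell cycle genes, the replication factor gene Mcm6 rose 2.32-fold and Mcm7 fell 1.43-fold, with 1 rise and 2 falls adjusted over the list alone (adjusted p = 0.309). Among 6 heat shock genes Hsp23 fell, with 1 rise and 1 fall adjusted over the list alone (adjusted p = 0.0570). With limma no member of the muscle (15), tracheal (9), axon guidance (15) and ribosomal protein (82) lists passed, over all genes or adjusted over the list alone. Their camera adjusted p-values were 0.431, 0.941, 0.586 and 0.909, and the tracheal list had a median of 0.07 beside a mean of -0.01. Among the members with the lowest p were pck (log2 change 0.28, adjusted p = 0.247), dysf (-0.35, 0.344), Con (0.60, 0.0931), fra (-0.36, 0.110) and RpL7-like (-0.29, 0.340). Con passed without wild-type late replicate 2 (adjusted p = 0.0292), and fra without wild-type early replicate 1 (log2 change -0.48, adjusted p = 0.0234). The muscle genes Prm (fitted log2 change -0.36, adjusted p = 0.253) and twi (-0.36, 0.325) had few early arrays above the floor. Prm counts as measured in neither genotype, so its value is no measured change, and that of twi is a lower bound of its size.

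On the values as deposited, 83 probe sets were called early, and 18 of 47 named early results lost their call, drpr, nerfin-1, brat, sna, para, Rop, rho, Sr-CI, vkg, crok, svp, Mcm7, E(spl)m3-HLH, Cyp4p2, PIG-V, CG5645, GstE3 and CG13159. With the floor doubled mwh (adjusted p = 0.0850), CG13159 (0.122) and vkg lost theirs, and with the generalised log E(spl)m3-HLH (0.103), Edg78E (0.104), PIG-V (0.0945), rho (0.0567), Rop (0.0887), sna (0.533), Sr-CI (0.0930) and CG13159 (0.363) did. Fitted on the 8 early arrays alone, CG14454 (0.0699), crok (0.117), nerfin-1 (0.0655), para (0.0904), rho (0.0630), Edg78E (0.225), Sr-CI (0.0740), vkg (0.215) and CG13159 (0.243) lost theirs. The proneural shift was lost without sca-gcm replicate 7 (adjusted p = 0.0797), and the midline shift without wild-type replicate 2 (0.0771) or 3 (0.0718) or sca-gcm replicate 7 (0.0717) or 8 (0.0958).

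In late embryos glial genes were higher in sca-gcm and neuronal genes lower. The calcium exchanger gene zyd, known from cortex glia, rose from the floor to 715 ± 82.8 (at least 6.90-fold), the Ig protein gene wrapper from 109 ± 11.6 to 465 ± 122 (at least 4.19-fold) and Mdr65, a transporter of barrier glia, from the floor to 365 ± 60.8 (at least 3.50-fold). The pan-neuronal gene elav fell from 917 ± 66.2 to 249.8 ± 93.4 (3.87-fold), its relative fne from 348.5 ± 75.3 to 105 ± 4.74 (at least 3.25-fold) and the synaptic vesicle gene nSyb from 312 ± 57.6 to the floor (at least 2.99-fold). The largest rise of a named gene measured in both groups was in polo, a mitotic kinase, from 170 ± 78.1 to 1173 ± 141 (7.43-fold), and the mitotic cyclin gene CycB rose from 713 ± 183 to 3542 ± 617 (5.02-fold). All values have n = 4, and the adjusted p-values of these genes, from limma, were 3.3e-06 or smaller.

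Of 14 glial genes tested late, 8 rose and 1 fell, over all genes and adjusted over the list alone. Besides those named and gcm, bnb rose from 445 ± 105 to 1412 ± 138 (3.23-fold), the neuronal and glial sodium pump subunit gene nrv2 1.43-fold, the glutamine synthetase gene Gs2 1.39-fold and the astrocyte gene alrm from 383.5 ± 50.3 to 473 ± 17.1 (1.24-fold, adjusted p = 0.018). The ETS factor gene pnt fell 1.73-fold, which was lost with the floor doubled (log2 change -0.11, adjusted p = 0.621, against -0.79). The list shifted up (median 0.39, camera adjusted p = 2.3e-05), with an adjusted p = 0.0341 with an estimated correlation. Without gcm the values were 2.6e-04 and 0.0488.

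Of 17 neuronal and synaptic genes, 10 fell and 1 rose late, and 11 fell and 1 rose adjusted over the list alone. Beside elav, fne and nSyb, the adhesion gene Nrx-1 fell to the floor (at least 2.15-fold), and para and Rop fell too, while the chaperone gene Csp rose by 1.06 on the log2 scale. The list shifted down (median -0.53, camera adjusted p = 9.4e-06, and adjusted p = 0.00526 with an estimated correlation). Of 21 proneural and neuroblast genes, 5 fell and none rose, also adjusted over the list alone. They included scrt (3.06-fold), the cell fate factor gene pros (1.66-fold), SoxN (1.36-fold) and Dr, which fell by 0.48 or more on the log2 scale to near the floor, and the list was not called (adjusted p = 0.0569). Of 14 Notch pathway and Enhancer of split genes, 6 fell and 1, N itself, rose, with 7 falls and 1 rise adjusted over the list alone. E(spl)m4-BFM fell from 475 ± 44.3 to 104 ± 2.19 (at least 4.55-fold), E(spl)m7-HLH 3.35-fold, E(spl)malpha-BFM to the floor (at least 2.28-fold) and E(spl)mbeta-HLH 1.53-fold. The shift was called (median -0.41, camera adjusted p = 0.00289, and adjusted p = 0.0282 with an estimated correlation).

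Of 17 cell cycle and replication genes, 7 rose late and 1, RnrL, fell, with 8 rises and 1 fall adjusted over the list alone. CycA rose from 259 ± 9.11 to 651 ± 31.5 (2.51-fold) and the mitotic exit gene fzy from 350.0 ± 40.3 to 820.5 ± 100 (2.34-fold). The shift up was called (median 0.21, camera adjusted p = 7.6e-04, and adjusted p = 0.0249 with an estimated correlation). Of 16 plasmatocyte and crystal cell genes, 6 fell and none rose, also adjusted over the list alone. The peroxidasin gene Pxn fell from 828 ± 207 to 260.1 ± 25.8 (3.13-fold), and the extracellular matrix genes SPARC (1.62-fold), vkg (1.59-fold), Glt (1.56-fold), Tig (1.48-fold) and LanB1 (1.47-fold) fell with it. The list shifted down (median -0.43, camera adjusted p = 0.00707; adjusted p = 0.348 with an estimated correlation).

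Of 16 septate junction genes, 4 rose and 1 fell late, also adjusted over the list alone. The Ig protein gene Lac rose from 160 ± 45.6 to 586 ± 82.7 (3.75-fold), crok from the floor (at least 2.30-fold), nrv2 as above and Nrg 1.40-fold, while vari fell 1.56-fold (camera adjusted p = 0.0810). In the 6 midline genes wrapper rose and Egfr (2.02-fold), rho (1.41-fold) and spi (1.36-fold) fell, as they did adjusted over the list alone (adjusted p = 0.734; median -0.21 but mean 0.04, with camera pointing down and fry up). Of 15 muscle genes, bap rose 1.46-fold and the muscle factor gene Mef2 (1.92-fold), bt (1.57-fold) and Mlp84B (1.31-fold) fell, with 1 rise and 4 falls adjusted over the list alone (adjusted p = 0.115, and 0.00824 with all probe sets of the genes). The cuticle genes TwdlT (at least 2.33-fold) and Gasp (1.41-fold) fell among 12 epidermal genes, also adjusted over the list alone (adjusted p = 0.309). Of 9 tracheal genes dysf fell 1.45-fold (adjusted p = 0.0494), none adjusted over the list alone (camera adjusted p = 0.792). Of 15 axon guidance genes, 2 rose and 4 fell, also adjusted over the list alone, among them Fas1 (1.62-fold higher), Ten-m (1.85-fold lower), Fas3 (1.76-fold lower) and side (at least 1.59-fold lower; list adjusted p = 0.448). Of 6 heat shock genes Hsp22 (2.47-fold) and Hsc70-4 (1.28-fold) rose and Hsp27 fell 1.75-fold, also adjusted over the list alone (adjusted p = 0.502). Of 82 ribosomal protein genes, 5 rose and 2 fell, with 4 rises adjusted over the list alone (adjusted p = 0.0810, and 0.0298 with all probe sets of the genes), among them RpS5b (log2 change 0.59), RpLP0-like (1.40-fold), RpS23 (1.28-fold) and RpL32 (1.24-fold). No fat body gene passed with limma (svp log2 change 0.51, adjusted p = 0.116; Adh -0.24, adjusted p = 0.667), but svp passed without wild-type replicate 2, its outlying array (0.82, adjusted p = 2.5e-04), and with array weights (0.65, adjusted p = 0.0183). The fat body list had a median of -0.06 and a mean of 0.04 (camera adjusted p = 0.884).

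Of the 7827 probe sets, 2077 changed late, 1067 higher and 1010 lower in sca-gcm, in 1802 named genes, with 495 at least 2-fold (276 higher, 219 lower). Arrays of the genotypes did not overlap for 1660 of them. Large rises outside the lists were in CG8157 (5.23-fold), the odorant-binding protein gene Obp99c (5.22-fold), Nagk (from 538 ± 30.0 to 2729 ± 66.4, 5.08-fold), the zinc transporter gene ZnT35C (4.98-fold), CR6900 (4.77-fold), CG5888 (4.59-fold), the solute carrier gene rumpel (from 186 ± 14.7 to 789 ± 49.1, 4.24-fold) and CG6891 (4.13-fold). From the floor rose smg, a translational repressor of maternal RNA (at least 6.98-fold, to 738 ± 181), Septin1 (at least 5.30-fold) and CG8745 (at least 4.54-fold). Large falls were in CG14989 (from 1496 ± 96.6 to 166 ± 26.2, 9.09-fold), CG13102 (5.29-fold), the neuropeptide gene Proc (5.01-fold, log2 change -2.33, adjusted p = 0.00867; -2.95 without sca-gcm replicate 9, and adjusted p = 0.0518 with the generalised log), GstE3 (4.73-fold), CG10621 (4.69-fold), MsrA (4.65-fold), Acbp5 (4.64-fold), CG8799 (4.37-fold), CG13920 (4.29-fold) and CG12523 (4.23-fold). CG34276 fell from 1727 ± 207 to the floor (at least 16.7-fold), as did the lipid-binding protein gene Npc2h (at least 6.86-fold), skl (at least 3.38-fold) and the cuticle gene Cpr23B (at least 3.28-fold).

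On the values as deposited the late median of all probe sets shifted by -0.13 on the log2 scale, with 549 higher and 1074 lower, and 16 of 81 named late results lost their call, alrm, Gs2, nrv2, LanB1, SoxN, spi, Nrg, Fas1, Hsc70-4, RpS5b, RpLP0-like, RpS23, RpL32, bap, dysf and Mlp84B. With the floor doubled, besides pnt, the calls of crok (log2 change 0.20, adjusted p = 0.324), Nrx-1 (-0.11, 0.244), E(spl)malpha-BFM (-0.19) and Dr (0.00) ended. With the generalised log, besides Proc, those of alrm (adjusted p = 0.158), dysf (0.0566), Gasp (0.495), SPARC (0.561), Tig (0.0932), vari (0.0700) and vkg (0.0585) did. Fitted on the 8 late arrays alone, alrm (0.0644), bap (0.0801), LanB1 (0.0932), side (0.0809), spi (0.140), TwdlT (0.106) and vari (0.0503) lost theirs. The call of SPARC was lost without any single late array (adjusted p 0.0502 to 0.064), and that of alrm without wild-type replicate 1 (0.0527) or 2 (0.0532).

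**Figure D2:**
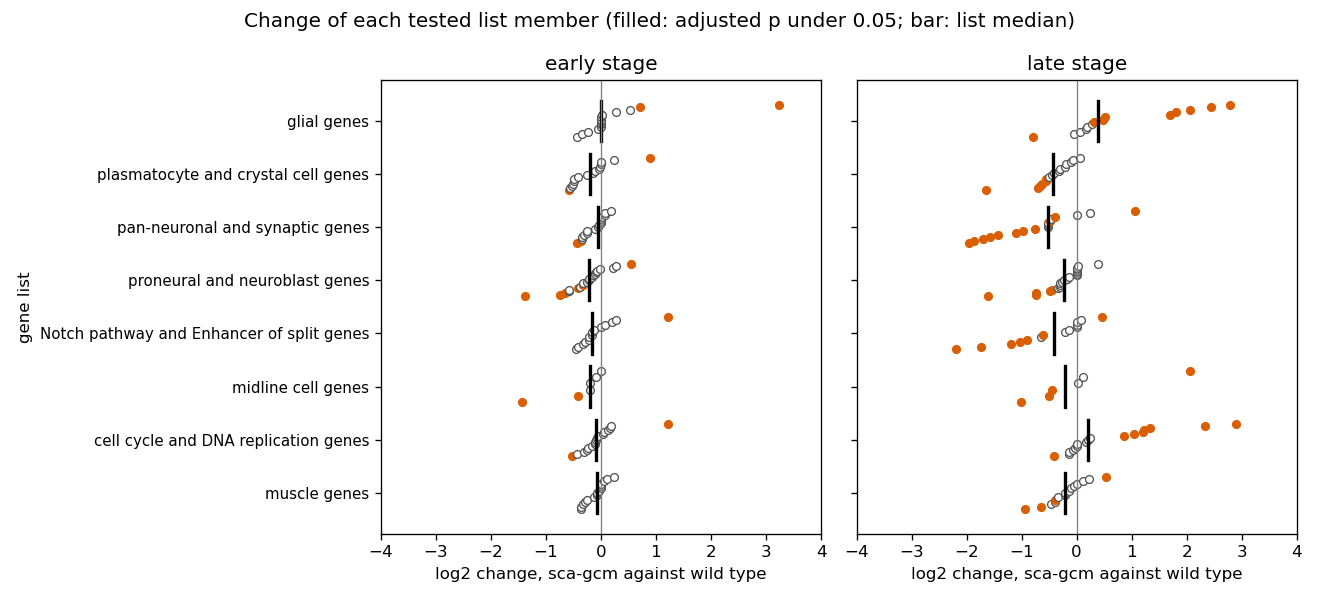
Log2 change in sca-gcm against wild type of each tested member of 8 gene lists, early and late; each point is a gene, filled where the adjusted p is under 0.05, and the black bar is the list median. Late medians are 0.39 for the glial and -0.53 for the neuronal list, against 0.00 and -0.06 early. Genes at the floor in both genotypes of a stage enter as 0. Over genes measured at each stage neither list was called for a difference (camera adjusted p = 0.993 and 0.171).

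The labels give both stages to part the period of glial determination from that of differentiated glia. Among genes above the floor in all 4 groups, the log2 effect of sca-gcm was higher late than early by 2.77 ± 0.32 for polo, 2.57 ± 0.29 for CG5888, 2.04 ± 0.25 for the glial gene bnb, 1.91 ± 0.23 for Lac, 0.76 ± 0.20 for nrv2 and 0.47 ± 0.13 for Gs2 (SE, n = 4 per group). For elav the difference was -1.70 ± 0.29 and for E(spl)m7-HLH -1.58 ± 0.18. For the glial genes zyd, wrapper and Mdr65 and the neuronal genes fne, nSyb and Nrx-1 neither genotype stood above the floor early, so an early effect could not be measured and the difference rests on the late change. This also holds for the most negative differences, CG34276 (-4.06 ± 0.12), CG14989 (-3.18 ± 0.14) and Npc2h (-2.78 ± 0.26), while CG43740 (-2.53 ± 0.10) was not measured late. The differences of Nplp3 (2.64 ± 0.62), msb1l (2.54 ± 0.16) and CG13101 (-2.78 ± 0.30) are lower bounds of their size.

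In all, 1048 probe sets were called for a difference of effect, 548 higher and 500 lower late, 422 of them by at least 2-fold (220 and 202). Over the 5134 above the floor in a group of each stage, a filter added after the data were seen, 607 were called, 399 higher and 208 lower. The Notch list differed downward (5 down and 1 up, 7 and 1 adjusted over the list alone; adjusted p = 0.00289, and adjusted p = 0.0282 with an estimated correlation), also over the genes measured at each stage (adjusted p = 1.8e-05, and adjusted p = 0.00853 with an estimated correlation), but the call was lost with the floor doubled (adjusted p = 0.20). The cell cycle list differed upward (6 up and none down, also adjusted over the list alone; adjusted p = 1.5e-04, and adjusted p = 0.0142 with an estimated correlation), also over the genes measured at each stage (adjusted p = 2.3e-04, and adjusted p = 0.0179 with an estimated correlation). The neuronal list was called downward over all its tested genes (7 down and 1 up, 8 and 1 adjusted over the list alone; adjusted p = 2.6e-04, and adjusted p = 0.0142 with an estimated correlation), but not over the 11 measured at each stage (adjusted p = 0.171). The glial list was called upward (6 up and 1 down, 7 and 2 adjusted over the list alone; adjusted p = 0.0136; adjusted p = 0.286 with an estimated correlation; without gcm 0.00169 and 0.0914), but not over the 8 measured at each stage (adjusted p = 0.993) or with the generalised log (0.0629). The heat shock list was called upward (3 up, and 4 up and 1 down adjusted over the list alone; adjusted p = 0.0214; adjusted p = 0.321 with an estimated correlation), but not over the 5 measured at each stage (adjusted p = 0.257), which leave out Hsp23, or with the generalised log (0.151). The plasmatocyte (adjusted p = 0.123), septate junction (0.144), proneural (0.792), midline (0.292), muscle (0.368), epidermal (0.389), tracheal (0.792), fat body (0.497; median -0.03, mean 0.33), axon guidance (0.694) and ribosomal protein (0.113, but 0.0416 with all probe sets of the genes) lists were not called. On the values as deposited 469 probe sets were called, 177 higher and 292 lower, with a median shift of -0.12, and the heat shock call was lost (adjusted p = 0.0707).

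Genes changed at both stages were compared next, with separate wild-type arrays on each side. Nagk was 5.28-fold higher early and 5.08-fold higher late, wisp 2.79-fold and at least 4.81-fold higher, CG8799 3.10-fold and 4.37-fold lower, GstE3 at least 3.11-fold and 4.73-fold lower, and scrt 2.59-fold and 3.06-fold lower. In all, 141 probe sets were higher in sca-gcm at both stages, where 47.3 would be met if the stages were independent, and 88 were lower at both, where 36.8 would be. Opposite changes were seen for 24, where 83.6 would be. On the values as deposited the 229 in the same direction fell to 36, where the early calls themselves fell from 632 to 83.

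Development in wild type, from early to late, gives the background for the late values. The cuticle protein gene TwdlF rose from 171 ± 14.9 to 9328 ± 826 (54.5-fold), and the Osiris family genes Osi7 (52.9-fold), Osi20 (36.0-fold) and Osi19 (31.9-fold), the troponin gene TpnC73F (37.6-fold) and the collagen gene Col4a1 (40.8-fold) rose with it. Among the largest falls were the Bearded family genes Tom (from 9316 ± 226 to 226 ± 83.6, 44.3-fold), Brd (34.1-fold) and Ocho (14.6-fold), and the Enhancer of split genes E(spl)mgamma-HLH (16.8-fold) and E(spl)malpha-BFM (13.4-fold). The mitotic kinase gene polo fell from 3778 ± 242 to 170 ± 78.1 (24.0-fold), and kuk, a nuclear membrane gene, 13.9-fold. CG13159, CG2961, CG15239 and CG2962 rose 31.4- to 49.4-fold, and CG13427 (55.3-fold), CG13465 (27.4-fold) and CG10035 (20.5-fold) fell (n = 4 per group).

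By lists, all 17 cell cycle genes fell during wild-type development, as did 12 of 14 Notch pathway genes and 17 of 21 proneural genes, whereas 14 of 17 neuronal, 12 of 15 muscle, 10 of 12 epidermal and 11 of 16 plasmatocyte genes rose. Of 14 glial genes 1 rose and 6 fell. In wild type 5287 probe sets changed, 2505 higher and 2782 lower late, with 2728 at least 2-fold (1246 and 1482). In sca-gcm 4947 changed, 2280 higher and 2667 lower late, with 2319 at least 2-fold (1037 and 1282). The split into higher and lower depends on the scaling: on the values as deposited, 4778 were higher and 870 lower late in wild type, with a median shift of 0.72, and 4136 and 763 in sca-gcm, with a shift of 0.57. With arrays scaled to the same median these shifts were 0.23 and 0.12.

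Across probe sets the late sca-gcm effect ran against the direction of wild-type development, as for polo and CycB, which fall in development and were higher in late sca-gcm, and Pxn and Gasp, which rise and were lower. The Notch and proneural lists did not follow this: 12 of 14 and 17 of 21 members fall in development, yet their median late changes were -0.41 and -0.23. Of the 2505 probe sets higher late in wild type, 668 were lower and 172 higher in late sca-gcm than in late wild type. Of the 2782 lower late in wild type, 620 were higher and 197 lower. The late wild-type arrays enter both sides of these counts, which by itself favours opposite changes, so only the correlations that follow, in which no array enters both sides, are free of it. Across probe sets, which are not independent replicates, r between the late sca-gcm effect and wild-type development was -0.295 (range -0.314 to -0.276 over 6 divisions of the wild-type arrays), and for the early effect 0.0217 (-0.0169 to 0.0479). The rank correlation of late arrays with the early wild-type arrays was 0.727 ± 0.00732 for sca-gcm and 0.694 ± 0.0143 for wild type (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays allow).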

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

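The tests of late glial levels against both wild-type groups, of the Notch, proneural and cell cycle genes that fall in development, and of the slope over all probe sets called early were chosen only after the changes had been seen; the other tests were written down before their values were, although CycA and other members of the cell cycle list were known to be higher by then.

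Chance was examined by regrouping the arrays. The real groups gave 632 changed probe sets early and 2077 late, and each was reached by 1 of 35 splits of the 8 arrays, the real one, with 14 and 26 as the highest of the others. A share of 1 of 35 is the smallest these splits allow. The other splits mix the genotypes, so a real difference widens their spread and keeps their counts low. Regrouping arrays cannot speak to a chance difference between embryo collections. Development, with 5287 in wild type and 4947 in sca-gcm, was likewise reached by 1 of 35 splits each, with 6 and 3 as the highest of the others and under the same limits. For the difference of effects the real grouping gave 1048 and 2 of 100 drawn splits gave as many, the real one included. The other one gave 1207. It exchanges the genotype of all 4 late arrays and of 1 early array, which turns the difference nearly into a sum of both effects, and the next highest was 956.

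The pattern seen across all probe sets is that late sca-gcm arrays stood closer to the early arrays than late wild-type arrays did. Delay or earlier staging of the late sca-gcm embryos might account for it, and would lower muscle and cuticle genes that rise in development. Their median late log2 changes were -0.27 (95% interval -0.43 to -0.12, 12 muscle genes) and -0.10 (-0.49 to 0.03, 9 epidermal and cuticle genes). The 95% intervals of medians and slopes in this part come from bootstrap draws of genes or probe sets. They measure the spread between genes, which are not independent, and not between arrays or embryos. The interval of the epidermal and cuticle genes spans 0, so the prediction for delay was not met in both lists. The neuronal and plasmatocyte lists were not part of that prediction. In wild-type development 14 of 17 neuronal genes rise and 3 fall, and 11 of 16 plasmatocyte genes rise and 2 fall. Their median late log2 changes, over all tested members, were -0.53 and -0.43. Both lie on the side that delay would give, which was not tested further. Delay cannot be told apart from an effect of gcm in any case, as each goes with the genotype. Delay would also raise genes that fall in development, but those of the Notch list had a median of -0.64 (-1.19 to 0.00, 11 genes) and those of the proneural list one of -0.24 (-0.32 to 0.00, 12 genes), on the other side of 0. Both intervals end at 0.00 because members at the floor in both late groups enter as 0, in the Notch list E(spl)m5-HLH, E(spl)mdelta-HLH and neur. A further fall of such genes could not be seen, so these bounds do not speak for delay. The cell cycle genes that fall in development had a median of 0.21 (-0.03 to 1.21, 17 genes), on the side that delay would give, though the interval spans 0. A mixture of the wild-type early and late states would put no gene above both wild-type groups. Of the 7 glial genes that rose late besides gcm, 5 (zyd, wrapper, Mdr65, alrm and Gs2, but not bnb and nrv2) stood above both, which argues against a mixture for these 5. The 7 were chosen as higher than late wild type, so they do not speak for other genes. Of all 2077 late calls, 442 (21.3%) stood above both wild-type groups and 325 (15.6%) below both. A further 690 lay between the groups and 620 were not told from early wild type. Delayed embryos could be at stages between the sampled ones, where a gene may stand above or below both wild-type groups. Neither the 5 glial genes nor these counts therefore speak against delay. A change of neural fate under gcm stays open, untested apart from the genotype.

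Another pattern is that smg, wisp, polo and CycB, all abundant in eggs, were higher in late sca-gcm embryos. Unfertilised eggs or arrested young embryos in the late collections might bring such RNA, and then other maternal transcripts would be higher as well. Over 11 others that could be tested of 24 listed, the median late log2 change was 0.0477 (95% interval -0.38 to 0.45), with aub (0.65) and plu (0.74, from near the floor) higher, gcl (-1.06) and yl (-0.56) lower and bcd at 0.05, so this stays open. Neural progenitors that go on dividing might also raise polo and CycB. The proneural list, however, had a median of -0.23 (-0.31 to 0.00, 21 genes), where members at the floor in both late groups set the bound of 0.00. The cell cycle list without polo and CycB had one of 0.16 (-0.06 to 1.05, 15 genes), which leaves this explanation open too. A biological effect of gcm on these 4 genes was not tested separately.

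A further pattern is that 229 probe sets (36 on the values as deposited) changed the same way at both stages, as did Nagk, 5.28-fold and 5.08-fold, and CG8799, 3.10-fold and 4.37-fold. The wild type is Oregon-R and the sca-gcm embryos come from other lines, so a strain difference might account for it and would be alike at both stages. The slope of the late on the early change was 1.03 (95% interval 0.89 to 1.17), but being called at both stages favours a slope near 1, so this decides nothing. Over all 632 probe sets called early the slope was 0.46 (0.39 to 0.53), which leaves open what the 229 share. A strain difference and a lasting response to gcm cannot be told apart, since no embryos with the driver or the construct alone are among the samples.

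In 11 of 291 groups of 4 arrays of named genes, 1 array stood far from the other 3, and chance does so in about 1 in 20 groups. On sca-gcm early replicate 10 this was the lowest value of PIG-V (159) and of para (722) and the highest of Rop (364) and pck (3159.6). On wild-type late replicate 2 it was the lowest of Nagk (493) and Tom (-5.33) and the highest of CG15239 (6943) and svp (1311). The others were the highest values of Proc on sca-gcm late replicate 9 (681), of Dr on wild-type late replicate 4 (175) and of CycA on sca-gcm late replicate 10 (698).

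For 79 of 131 named genes the test of the difference in limma called the sca-gcm effect different between the stages, 39 with a higher and 40 with a lower value late. In 33 of them all 4 groups stood above the floor, and the late minus early log2 values were 2.77 for polo, 2.57 for CG5888, 2.33 for CG8157, 2.29 for CycB, 2.04 for bnb, 1.91 for Lac, 1.6 for CG33272, 1.57 for Mcm7, 1.49 for CycA, 1.48 for Tsp42Ec, 1.45 for GstE6, 1.38 for svp, 1.36 for CR6900, 1.30 for fzy, 1.13 for CG6891, 0.82 for Hsp22, 0.77 for Fas1, 0.76 for nrv2, 0.65 for RpS5b, 0.47 for Gs2, 0.46 for Nrg, 0.38 for Hsc70-4, -0.50 for CG8799, -0.64 for pros, -0.69 for E(spl)mbeta-HLH, -0.91 for Mef2, -1.21 for Argk1, -1.30 for LysD, -1.41 for hpRNA:CR18854, -1.43 for DhpD, -1.58 for E(spl)m7-HLH, -1.70 for elav and -2.06 for CG10621. In 10 more a group at the floor makes the value a lower bound of its size, 2.64 for Nplp3, 2.54 for msb1l, 2.38 for Septin1, 2.05 for smg, 1.10 for Aplip1, 1.04 for Hsc70-2, 0.93 for CG10936, -0.98 for E(spl)malpha-BFM, -1.85 for E(spl)m4-BFM and -2.78 for CG13101.

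In 23 others neither genotype stood above the floor early, so the value rests on the late change: 2.79 for zyd, 2.38 for Obp99c, 2.07 for wrapper, 1.98 for rumpel, 1.95 for CG8745, 1.81 for Mdr65, -0.49 for Gasp, -0.56 for Tig, -0.64 for Glt, -0.64 for vari, -0.65 for bt, -1.10 for Nrx-1, -1.54 for nSyb, -1.56 for skl, -1.69 for Cpr23B, -1.70 for fne, -1.80 for MsrA, -2.21 for Acbp5, -2.31 for CG12523, -2.44 for CG13102, -2.78 for Npc2h, -3.18 for CG14989 and -4.06 for CG34276. A fitted early part from arrays around the floor enters some of them, as for MsrA, with -0.42 early and -2.22 late. In 8 neither genotype stood above the floor late, so the value rests on the early change, with its sign turned: 2.09 for CG33090, 2.04 for Hsp23, 0.75 for nerfin-1, -0.54 for sna, -1.09 for Sr-CI, -1.41 for mwh, -1.52 for PIG-V and -2.53 for CG43740. In 5 a group at the floor leaves even the sign open, 2.02 for ZnT35C, -0.80 for gcm, -1.13 for Pxn, -1.15 for E(spl)m3-HLH and -1.33 for CG13920; late wild-type gcm lay between 11.9 and 50.8 before the floor was applied.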

How the results depend on the processing

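Quantile normalization within each stage, the glial list without gcm and the filter on probe sets above the floor in a group of each stage were chosen after the data were seen. Of 158 called results for named genes, 108 kept direction and call under every alternative in which they were tested. The call was lost under at least 1 for 50 (12 of them when 1 array was left out) and 0 reversed. Of 12 results not called, 4 passed under at least 1. Stricter thresholds were not applied to named genes, and replicate blocks covered only development and the difference. A probe set that failed the filter of a setting was not tested there and does not count as a lost call. Signal over background is a limit, as 6211 of 14038 probe sets stayed near the floor and folds from or to it are lower bounds. The cause of each change below was not tested, except where a stricter threshold or fewer arrays bring it about. List values are camera adjusted p-values.

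On the values as deposited, 83 probe sets changed early, 469 differed between stages and 36 were shared between stages in the same direction; the direction turned for the septate junction list early (0.967), the tracheal list early (0.967), late (0.985) and in the difference (0.967), and the ribosomal list early (0.153). With arrays scaled to the same median the ribosomal list turned early (0.164). With the floor doubled the epidermal list turned early (0.924) and r of the early effect with development was 0.0652; with the floor halved the tracheal list turned early (0.905); with the generalised log the epidermal (0.983) and tracheal (0.969) lists did. Within-stage quantile normalization gave 401 changed early, and turned the septate junction (0.981) and tracheal (0.981) lists early. With all probe sets 14 list shifts were called, with the muscle list late (0.00824) and the ribosomal list late (0.0298) and in the difference (0.0416) added and the proneural list early (0.158) lost, and the septate junction (0.910), tracheal (0.979) and ribosomal (0.910) lists turned early. Fry called 22 of 45 list shifts and turned the midline list late (0.480), the estimated correlation called 7, and the preset correlation called 12.

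With only probe sets above the floor in a group of each stage 607 differed between stages, and the calls of the glial (0.993), neuronal (0.171) and heat shock (0.257) differences ended, as genes not measured at 1 stage were left out.

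An adjusted p under 0.01 gave 306 early, 1347 late and 632 for the difference. At least 2-fold left 113, 495, 422, 2728 in wild-type and 2319 in sca-gcm development. Replicate numbers did not pair the arrays (r of equal numbers -0.0908 to 0.0851, with 3 of 8 as the best match); as a block they gave 817 for the difference, 5202 and 4842 for development.

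Leaving out each array in turn gave 485 to 650 changed early, 1812 to 2064 late and 942 to 1103 for the difference. Directions turned within these ranges: sca late (log2 change -0.46 to 0.12), and the lists muscle early (0.207 to 0.942), epidermal early (0.382 to 0.998), tracheal early (0.441 to 0.964), ribosomal early (0.825 to 0.973), fat body late (0.502 to 0.965) and tracheal difference (0.566 to 0.946). The r of the late effect with development was -0.298 to -0.267. Early calls that ended without 1 array, with their adjusted p, were para (any sca-gcm early array or wild-type early 2, 3 or 4; 0.0591 to 0.105), rho (sca-gcm early 7 or 8, wild-type early 1, 2 or 3; 0.0582 to 0.0995), svp (sca-gcm early 8, 9 or 10, wild-type early 1, 2 or 3; 0.0552 to 0.0655), Edg78E (any wild-type early array, sca-gcm early 7, sca-gcm late 7, wild-type late 3; 0.0603 to 0.0826), CG13159 (any sca-gcm early array, wild-type early 3 or 4, sca-gcm late 7, 8 or 9, wild-type late 1; 0.0501 to 0.118), Rop (any but sca-gcm early 10 and wild-type late 4; 0.0516 to 0.112) and vkg (any but wild-type early 2 and wild-type late 3; 0.051 to 0.126). Late ones were spi (sca-gcm late 9 or 10, wild-type late 1 or 4; 0.0694 to 0.099), Mlp84B (any wild-type late array, sca-gcm late 8, 9 or 10, sca-gcm early 8, wild-type early 1 or 4; 0.0504 to 0.130), dysf (any wild-type early or sca-gcm late array, wild-type late 2, 3 or 4, sca-gcm early 8 or 10; 0.0522 to 0.135), SPARC and alrm. List calls that ended under another setting were the Notch difference (0.20, floor doubled) and, with the generalised log, the glial (0.0629) and heat shock (0.151) differences; the proneural call early ended with all probe sets (0.158).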

Other observations

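The genes and probe sets in this part were chosen after their values were seen, and no hypothesis is tested on them. Some genes changed in opposite directions at the stages, each change with an adjusted p under the threshold in limma. The RNA-binding protein gene shep was higher in early sca-gcm embryos, with a log2 change of at least 1.11 from near the floor, and lower in late ones, with -0.97. The cytokinesis gene tum was lower early (-0.52) and higher late (1.32), as was the nuclear membrane gene kuk (-0.42 and 1.37), and the fatty acid binding protein gene fabp went from -1.09 to 0.59.

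Large changes were also seen in probe sets that could not be tied to 1 gene. The probe set W_at stood at 112 ± 8.97 in early wild type and 1638 ± 349 in early sca-gcm, a log2 change of 3.85, and at 119 ± 18.1, near the floor, and 231 ± 8.44 late. Its name also fits the strain marker w, so a difference between the strains cannot be told apart from a response to gcm there. The probe set CAF1_at stood at 277 ± 72.8 and 1828 ± 68.8 early, and at 105.01 ± 3.88 and 1156 ± 162 late (SD, n = 4).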
